A study of Mus musculus with 8 samples.

How the data were processed

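Messenger RNA was measured in cultured mouse macrophages on 8 Illumina mouse BeadChip arrays, all on 1 chip. Per the labels' protocols, C57BL/6 bone marrow cells were grown into macrophages with M-CSF at 20 ng/mL and 10% serum. They were transfected with a mimic of the microRNA miR-511-3p or with a control, which the labels call a microRNA mock and tag mi-neg, 48 h before stimulation. LPS, a bacterial cell wall component, was given at 100 ng/mL for 6 h, and the cytokine IL-4 at 20 ng/mL for 24 h. Wild-type (WT) cells were kept in media, LPS or IL-4, and Mrc1-knockout (KO) cells in media alone. Each of the 4 contexts had 1 mock and 1 mimic array, so every group was 1 array. The labels do not say whether arrays came from separate cultures, and p-values here measure only the spread between these samples.

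The deposited scanner table held, per probe of 50 nucleotides and per array, an intensity averaged over beads, the bead standard error, the number of beads and a detection p-value against negative controls, per the file headers. GenomeStudio 2011.1 made it, per the submitters' processing notes. The intensity was linear and had not been normalized between arrays, and the deposited values of the series held the same intensities, with a largest difference of 0. The scanner table also held 64 columns of 16 arrays on 2 other chips. Their names follow the same scheme of genotype, transfection and stimulation but match no sample's labels, so they were not used, and whether they are further replicates of these groups is not known here. Of the 25697 probes, 23788 were named through their Entrez ID, 685 through a RefSeq accession and 651 through a symbol or synonym, using a table of GRCm38.p6 genes, and 573 kept the file's name. The genome build of the file's probe coordinates is not given in the sources used here.

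Log2 values were made with neqc in limma 3.58.1 (R 4.3.3, with the package data.table at version 1.17.8), which removes background inferred from the detection p-values, adds an offset of 16 and quantile-normalizes. A probe was kept when its detection p was under 0.01 on at least 2 arrays, which left 11417 probes. A gene took its kept probe with the highest mean, a choice that applied to 2174 of the 8386 genes tested. Chip position differed for every array and could not be a block.

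The model had a term for each context and 1 for the mimic, fitted with lmFit and eBayes, with 3 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The mimic's effect is therefore judged by how alike the 4 mock and mimic pairs moved. LPS, IL-4 and the knockout were each compared with WT media, 2 arrays against 2. These 3 comparisons share the WT media arrays, so their gene lists were not set against each other. Each of 3 interaction models added a term for an extra mimic response in 1 context, with 2 residual degrees of freedom. That makes 7 tests of 8386 genes. Within 1 context a log2 ratio of 1 array to 1 has no test and is given as a value. An exact sign-flip test of 4 pairs cannot go below a two-sided p of 0.125, so genes moving 1 way in all 4 pairs were counted instead.

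Groups of genes were 24 lists fixed before the data were examined, as were the model, the filter, the thresholds, the rule for naming genes and most of the alternatives. Each list with at least 3 tested genes, 20 lists, was tested with camera at its preset correlation of 0.01, in each of 4 comparisons. Camera with an estimated correlation and fry were alternatives. The first of these also gave a higher p where the estimated correlation was below the preset. For fibroblast genes under the mimic, with an estimated correlation of -0.017, camera's unadjusted p went from 1.8e-05 to 0.0196. A call lost in that alternative therefore does not by itself show that the list's genes vary together. Within a context, a list's median was placed as a percentile among 10000 random lists of the same size matched on mean expression. Mrc1, Rock2 and Ccl2 were always named. Beside them, the 10 genes that rose most and the 10 that fell most were named, if past the threshold, alike in direction in every pair of arrays, and detected on every array of the higher side. Where fewer passed, the largest of the rest were given as values. From each list up to 4 past the threshold were named, otherwise up to 2 as values. Some list members' values are not reported here. A gene not detected on any array of its dimmer side has a fold given as "at least". That bound sets the brighter side's mean against, per array, the higher of the lowest signal among detected probes and the probe's own signal.

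The scripts were tested on simulated data with the 8386 real genes' means and spreads and 50 genes changed at each fold size. For the mimic's effect, 34%, 78%, 96% and 100% of genes changed 1.5, 2, 3 and 4-fold were called, with 8 false calls. For LPS 4%, 46%, 68% and 82% were called, with 3 false calls. Only 200 genes were changed there, against 4162 called for LPS in the real data. The adjusted p depends on how many genes change, so these shares do not carry over to the real LPS test. For IL-4 2%, 54%, 74% and 88% were called, with 8 false calls, and for the knockout 4%, 46%, 72% and 86%, with 3. With no change simulated, 0 genes were called. The 3 interaction tests called 0 of the genes changed 1.5 to 4-fold. In a second simulation with folds up to 64, added after that result, genes changed 4-fold were called in 64% of cases for LPS, 52% for IL-4 and 62% for the knockout. That simulation also held genes changed 16 and 64-fold, and the adjusted p of a gene depends on the other genes. The same 4-fold change was called in 0% of cases without them. These shares are therefore not the power of the real interaction tests. Camera called the simulated list that was lowered and 0 of 20 lists that were not. The simulated genes varied independently, while the interferon-stimulated genes had an estimated correlation of 0.276. Camera's false calls on lists of genes that vary together were therefore not tested.

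Alternatives changed the background correction (normexp with offset 50, or none), the scaling (median scaling, or deposited intensities without normalization), the filter (none, or detected on all 8 arrays), the use of every probe, the variance model, the arrays included and the context term. Leaving out an array left 2 residual degrees of freedom. In the LPS, IL-4 and knockout comparisons a lone array of a context was then assumed to vary like the others. For the mimic's effect it was fitted by its own context term, so leaving out either array was the same fit as leaving out its pair. The fit on WT arrays only was likewise the same as leaving out either knockout array. A planned analysis of microRNA seed matches in 3′ untranslated regions was not run, because their sequences were not in the reference used here. Figures were drawn with matplotlib 3.10.9.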

Results

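The 8 arrays measured macrophages in 4 contexts (WT media, WT LPS, WT IL-4 and Mrc1-KO media), each with 1 mock and 1 miR-511-3p mimic array. On the mock arrays 38.9%, 35.7%, 40.6% and 38.9% of probes were detected in that order of contexts, and on the mimic arrays 45.1%, 36.4%, 41.1% and 39.9%. The WT media mimic array was the brightest, with a mean intensity of 360.4 against 271 for its mock partner, while the other 6 lay between 280.3 and 303. Each intensity rested on a median of 31 to 36 beads per probe. No group had a replicate array among those the labels identify, and the number of arrays limits the precision of every value.

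Mrc1 encodes the macrophage mannose receptor, and miR-511 lies within an intron of it. Its probe intensity was 842 on the WT mock media array and 774 on the mimic one, 343 and 199 in LPS, and 3998 and 3222 in IL-4. On the KO mock and mimic arrays it was 98.1 and 92, with detection p of 0.0927 and 0.357, so the probe was not detected there. The file places it on chromosome 2 from 14253066 to 14253115, on a build that is not given in the sources used here. The labels do not say which part of Mrc1 was removed, so whether the probe lies in that part is not known here.

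The first comparison asks what the miR-511-3p mimic changed across the 4 contexts. Gsta3, a glutathione S-transferase that couples glutathione to reactive compounds, rose 6.60-fold, by 2.72 ± 0.12 on the log2 scale (SE, n = 4 pairs, limma adjusted p = 6.0e-05). Over its alternatives the log2 change of Gsta3 ran from 1.73, without background correction, to 2.82. Across all genes 71 changed, 30 up and 41 down, and 4 and 9 of these by more than 2-fold. At an unadjusted p under 0.05 there were 1517. Of the named genes Prr33, Ostm1 and Itgam fell most. The 2 reported targets of the microRNA, Rock2 and Ccl2, were lower on average by the probes used but did not pass.

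Gsta3 was higher in each pair, by 2.94 in WT media, 2.88 in LPS, 2.53 in IL-4 and 2.55 in the knockout on the log2 scale. Its intensity was 149 and 942 in the WT media pair, 108 and 352 in LPS, 104 and 233 in IL-4, and 171 and 556 in the knockout, and it was detected on 3 of the 4 mock arrays. It was not detected on the IL-4 mock array, so the value of 2.53 there is a difference from a probe not above background. A second Gsta3 probe, which lies downstream of the first on chromosome 1 by the file's coordinates, was detected on 0 of 8 arrays. Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, rose 2.20-fold (1.14 ± 0.16, adjusted p = 0.0350). Mgll, the lipase that breaks down monoacylglycerols, rose 2.20-fold (1.14 ± 0.12, adjusted p = 0.0229). Cyp4f18, a cytochrome P450 that inactivates leukotriene B4, rose 2.13-fold and Slc22a4, an ergothioneine transporter, 1.92-fold. The signalling adaptor Crk rose 1.91-fold, the retroviral element named Iap 1.84-fold, the ubiquitin ligase Rnf128 1.82-fold, the first haem synthesis enzyme Alas1 1.81-fold and the actin-associated Pdlim4 1.80-fold. The mock side of Mgll, Slc22a4 and Rnf128 was detected on 3 of 4 arrays.

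Prr33 fell 2.30-fold (-1.20 ± 0.15, adjusted p = 0.0285). Ostm1, the partner of a lysosomal chloride transporter, fell 2.12-fold (-1.08 ± 0.12, adjusted p = 0.0229). Itgam, the CD11b integrin chain of myeloid cells, fell 2.10-fold (-1.07 ± 0.17, adjusted p = 0.0359). The calcium pump Atp2a3 fell 2.10-fold, the inhibitory receptor Milr1 2.07-fold and Gas6, a ligand of the receptors that clear dead cells, 2.04-fold. Lbr, the lamin B receptor, fell 2.02-fold, the endolysosomal channel Mcoln3 2.01-fold, the lysosomal transporter Slc46a3 2.01-fold and the glutathione enzyme Mgst3 1.95-fold. Atp2a3 and Slc46a3 were detected on 3 of the 4 mimic arrays.

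Of the genes always named, Mrc1 gave -0.59 ± 0.18 on the log2 scale (adjusted p = 0.148), with pair values of -0.75 in WT media, -1.22 in LPS, -0.21 in IL-4 and -0.18 in the knockout, where it is at background. Rock2, a protein kinase, gave -0.42 ± 0.16 (adjusted p = 0.222), with 0.08, -0.89, -0.50 and -0.35 in the same order. Its LPS value compares a detected mock probe (122) with an undetected mimic one (106). Ccl2, a monocyte chemokine, gave -0.35 ± 0.19 (adjusted p = 0.368), with 0.24, -0.95, -0.65 and -0.06. In LPS its intensity was 3859.6 (bead SE 124) on the mock and 1957 (bead SE 108) on the mimic array.

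The mimic's count of 71 rested on all 4 pairs. Without any 1 array of the WT media, LPS or knockout pair 1 gene passed, and without either IL-4 array 2 did, Gsta3 and Prr33. Gsta3 passed in each of those fits. With any 1 pair left out all 71 kept their direction, with a median size of 0.80 to 0.84, against 0.83 with all pairs. These genes were selected using all 4 pairs, so their kept direction and size exclude nothing. Their median SE was 0.117 to 0.163, against 0.121, and the residual degrees of freedom were 2 in place of 3. Other settings gave between 0 and 371 genes.

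Of 20 lists, 3 moved under the mimic by camera. Interferon-stimulated genes were lower in 33 of 35 cases, with a median of -0.20 (camera adjusted p = 1.3e-05; adjusted p = 0.645 with an estimated correlation). None of them passed on its own over all genes by limma, and 7 fell adjusted over the list alone; Irf7, a master regulator of the interferon response, gave -0.75 and the antiviral Oas3 -0.61 (adjusted p = 0.0784). Fibroblast and stromal genes were lower in 14 of 15 cases, with a median of -0.28 (adjusted p = 1.8e-04; adjusted p = 0.391 with an estimated correlation). Among them 0 passed over all genes and 4 fell adjusted over the list alone, and the collagens Col1a1 and Col6a1 gave -0.65 and -0.58. Neutrophil and progenitor genes were higher in 5 of 6 cases, with a median of 0.46 (adjusted p = 0.00761; adjusted p = 0.645 with an estimated correlation). S100a8, a calcium-binding alarmin, rose 1.75-fold (0.81 ± 0.13), and 3 of the 6 rose adjusted over the list alone. That list's call was lost in 4 of 11 alternatives, with medians from -0.04, where no filter let 15 genes in, to 0.62 (adjusted p 9.4e-04 to 0.645). The interferon and fibroblast calls were lost in 2 and 1 of 11.

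The lists that bear on polarization did not pass camera for the mimic. Of 26 inflammatory cytokines and chemokines 0 passed and 20 were lower, with a median of -0.19 (adjusted p = 0.105), and Ccl5 gave 0.51 and Csf2 -0.38. Of 28 NF-kB targets and M1 effectors 0 passed and 21 were lower, with a median of -0.15 (adjusted p = 0.105). The formyl peptide receptor Fpr2 gave 1.00 and the costimulatory Cd86 -0.60, and 1 rose and 1 fell adjusted over the list alone. Of 26 IL-4-induced genes 1 fell, the crosslinking enzyme Tgm2 (-0.80), while the median was 0.10 (adjusted p = 0.176) and 4 rose and 2 fell adjusted over the list alone. Of 10 MHC class II genes 0 passed (adjusted p = 0.409) and 1 fell adjusted over the list alone. Their median was -0.05, against 0.05 with median scaling and 0.04 without normalization, but less the median of all genes it was -0.05, -0.05 and -0.03.

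Among the other lists, 1 of 24 stress and oxidative response genes rose under the mimic, Gclm, and the thioredoxin reductase Txnrd1 gave 0.81 (adjusted p = 0.0956). One of 18 glycolysis and hypoxia genes fell, Pdk1 (-0.64), a kinase that restrains pyruvate use by mitochondria. Gas6 fell among 27 scavenging and lysosome genes, and Itgam among 23 macrophage identity genes, where the median was 0.00, the mean -0.03 and camera's direction down. None of 29 Toll-like receptor genes passed (Map3k7 0.79, Cd14 -0.67), nor of 23 RhoA and actin genes (Actb -0.51, Rhob 0.50), nor of 14 microRNA machinery genes (Cnot7 -0.42, Tnrc6a 0.40; median 0.02, camera's direction down). The same held for 26 cell cycle genes (Birc5 -0.48, Plk1 -0.46), 19 cholesterol genes (Lss -0.41) and 15 LXR and lipid genes (Plin2 0.50, Lpcat3 0.40). It also held for 22 remodelling genes (Mmp13 0.53, Mmp12 0.48), 13 housekeeping genes (Tfrc 0.73, Actb -0.51) and 4 sex-linked genes (Eif2s3y 0.51, Kdm5d 0.40). Both sex-linked values lean on the WT media pair. The log2 levels on its mock and mimic arrays were 8.57 and 9.76 for Eif2s3y and 5.77 and 7.06 for Kdm5d. On the arrays of the other contexts they ran from 8.47 to 8.82 and from 5.29 to 6.02. Too few genes of 4 marker lists were detected for camera. The dendritic list had Itgax (0.45), the lymphocyte list Il7r (0.43) and Lck (-0.03), the mast cell list Hdc (-0.14), and the erythroid list no gene. Adjusted over the list alone, 1 Toll-like receptor gene, 1 RhoA gene and 2 macrophage identity genes fell, and 2 stress genes rose. In the same way 2 LXR genes rose and 1 fell, 3 housekeeping genes rose and 3 fell, and 1 microRNA gene moved each way. Itgax was the only tested gene of its list, so its limma p under 0.05 there is unadjusted.

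The mimic's response per context, 1 array against 1, was widest in WT media, where the log2 ratios had an SD of 0.47, against 0.38 in LPS, 0.31 in IL-4 and 0.30 in the knockout. In the LPS pair the cytokine list had a median of -0.48, lower than all 10000 random lists (percentile 0), and 19 of 26 genes were lower. With detection required on all 8 arrays the median was -0.19 over 10 genes. Random lists take genes as independent, while the estimated correlation within this list was 0.232, and 1 array against 1 cannot part the mimic from a difference between 2 cultures. The percentiles in this paragraph are therefore no test of the mimic. In that pair Csf2 gave -1.36, Il12a -1.21, Csf3 -1.17, Cxcl9 -1.07, Cxcl2 -1.05, Il6 -0.90, Cxcl1 -0.85, Il27 -0.81 and Tnf -0.43, while 7 were higher, among them Tnfsf15 at 0.45, Ccl5 at 0.18, Il10 at 0.17 and Ccl3 at 0.12. Lists of other kinds also lay far out in the LPS pair, with smaller medians: cell cycle genes at -0.32 (percentile 0.01), remodelling genes at -0.29 (0), MHC class II genes at -0.41 (0.05) and cholesterol genes at 0.31 (99.9). In the WT media pair the cytokine median was 0.15 (percentile 96.6), in IL-4 -0.03 (31.7) and in the knockout -0.04 (26.9). NF-kB targets had a median of -0.30 in the LPS pair (percentile 0.01), with 25 of 28 lower. Interferon-stimulated genes had medians of -0.04 in WT media (percentile 49.9), -0.28 in LPS (0), -0.54 in IL-4 (0) and -0.18 in the knockout (0.01). IL-4-induced genes had medians of 0.16 in the IL-4 pair (percentile 99.2), 0.12 in LPS (93.1), 0.03 in WT media (65.9) and 0.08 in the knockout (85.3). Fibroblast genes had medians of -0.31, -0.31, -0.22 and -0.31 in WT media, LPS, IL-4 and the knockout, and neutrophil genes 0.51, 0.06, 0.80 and 0.49. Values per context were planned for all lists, while the closer look at the LPS pair and the single genes were chosen after the values were seen.

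**Figure D1:**
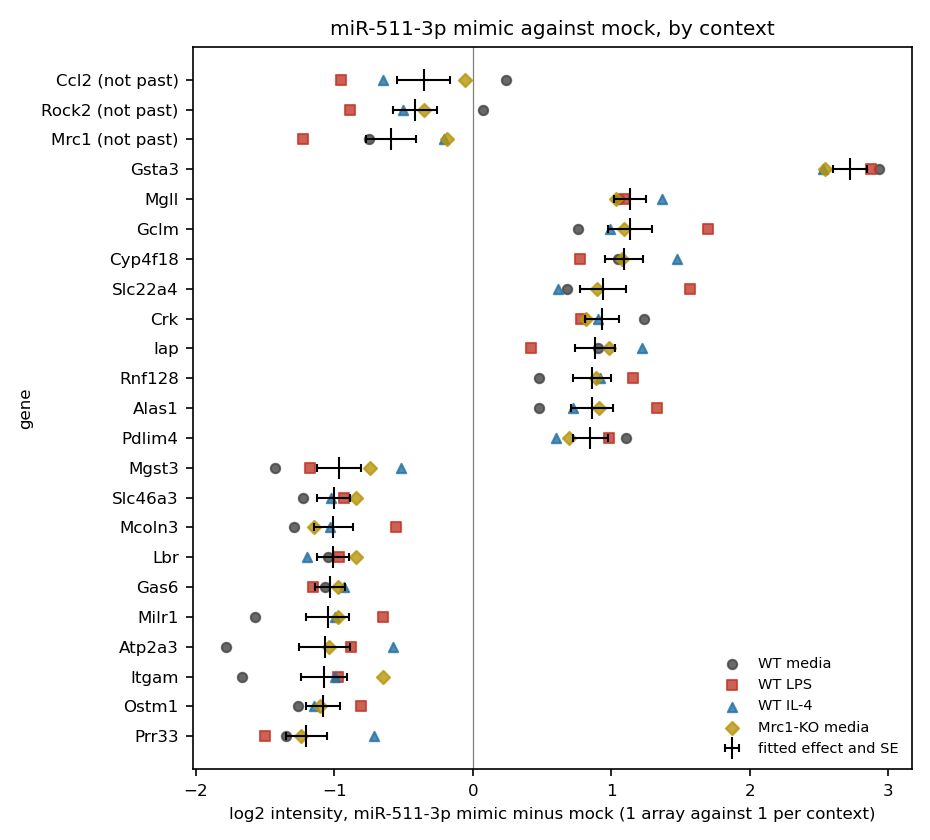
Log2 ratio of mimic to mock intensity (horizontal axis) for the genes named for the mimic, 1 point per context and 1 bar for the mean ± SE. Gsta3 lay between 2.53 and 2.94 in the 4 contexts, while the points of Rock2 and Ccl2 lie on both sides of 0.

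**Figure D2:**
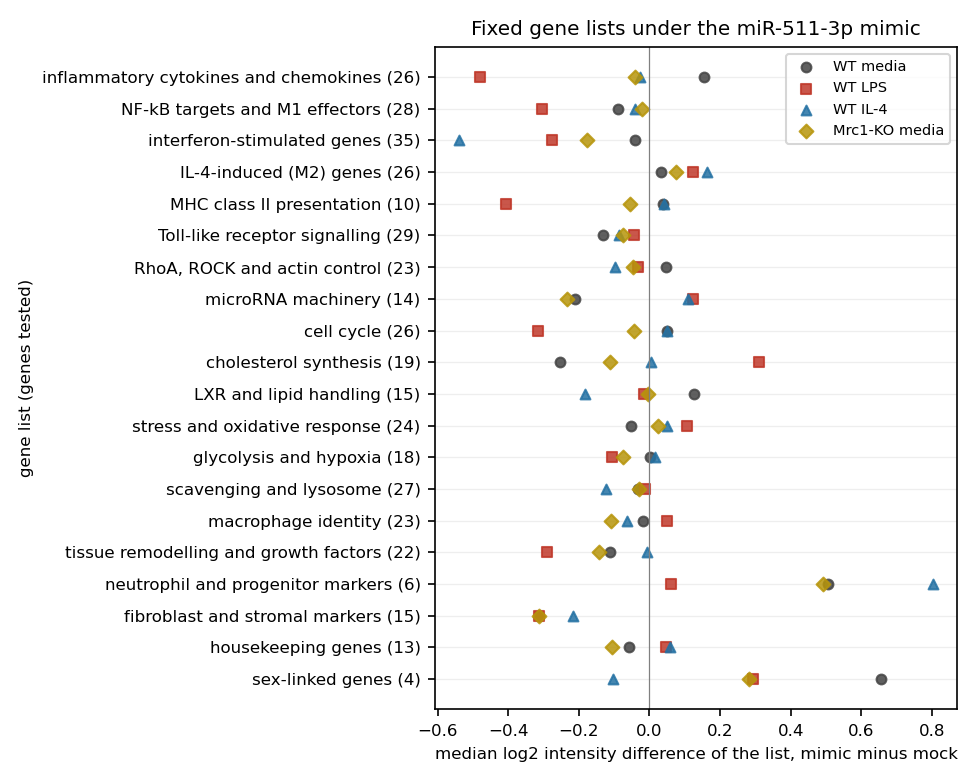
Median log2 ratio of mimic to mock (horizontal axis) of each fixed list with at least 3 tested genes, 1 point per context. The cytokine list had its lowest median, -0.48, in LPS, and the interferon-stimulated list its lowest, -0.54, in IL-4.

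Whether the mimic acted differently in LPS, IL-4 or the knockout was asked with the 3 interaction tests. WT media, where the log2 ratios had the widest SD (0.47), had no such test. By limma 0 genes passed for LPS, IL-4 or the knockout, with 614, 174 and 108 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.504, 1.00 and 1.00. Differences between contexts in the cytokine and interferon lists were therefore not shown for any single gene. Across genes, which are not independent replicates, the mimic's log2 ratios in 2 contexts correlated with a mean Pearson's r of 0.299 over the 6 context pairs (0.204 to 0.428). In all, 2350 genes (28.0%) moved 1 way in all 4 pairs, where chance gives 1 gene in 8.

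LPS comparisons show the M1 side of polarization, named in the series title, in WT cells. LPS changed 4162 of the 8386 genes (limma), 1629 up and 2533 down, and 866 and 1104 of these by more than 2-fold. The chemokine Cxcl10 rose 270-fold (8.08 ± 0.35 on the log2 scale, SE, 2 arrays against 2, adjusted p = 6.5e-07). Every tested gene of 3 lists rose: 26 cytokines, 28 NF-kB targets and 35 interferon-stimulated genes.

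The neutrophil-attracting chemokines Cxcl2 and Cxcl1 rose 165-fold and 124-fold after LPS, and the T cell chemokine Cxcl9 141-fold. Il1a and Il1b, the interleukin-1 cytokines, rose 152-fold and 124-fold, the activation marker Cd69 143-fold and the cytokine signal inhibitor Socs3 133-fold (7.05 ± 0.20). The acute phase protein Saa3 rose 132-fold and the mycobacterial lipid receptor Clec4e 112-fold. Il1a, Cd69 and Cxcl9 were detected on 1 of the 2 media arrays. The chemokine receptor Cxcr4 fell 49.2-fold (-5.62 ± 0.28), St6gal1, which adds sialic acid to glycoproteins, 29.0-fold, and the lysoplasmalogen enzyme Tmem86a 26.0-fold. Ypel3 fell 23.8-fold, Rassf3 21.8-fold and Slc46a3 19.4-fold. The stress-response gene Sesn1 fell at least 22.8-fold, the glycan-branching enzyme Gcnt1 at least 19.6-fold, the palmitoyltransferase Zdhhc14 at least 19.4-fold and Pald1 at least 13.1-fold, being detected on 0 of 2 LPS arrays. Cxcr4, St6gal1, Rassf3 and Slc46a3 were detected on 1 of 2. Ccl2 rose 52.8-fold (5.72 ± 0.27) and Mrc1 fell 2.96-fold (-1.57 ± 0.26, adjusted p = 0.00112), while Rock2 gave -0.15 ± 0.22 (adjusted p = 0.605).

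Camera called 6 lists for LPS, and 0 of them with an estimated correlation. The median log2 change was 4.08 for cytokines (3.82 with bounded genes at their bound; adjusted p = 5.9e-21; adjusted p = 0.157 with an estimated correlation). It was 3.70 for NF-kB targets (adjusted p = 4.6e-24; adjusted p = 0.140 with an estimated correlation), where Fpr2 rose 92.2-fold and the CD40 receptor gene Cd40 70.7-fold. Interferon-stimulated genes had a median of 3.42 (adjusted p = 5.9e-25; adjusted p = 0.157 with an estimated correlation), with Ifi205 at 101-fold, the ubiquitin-like Isg15 at 65.1-fold, Gbp2 at 64.8-fold and Oasl1 at 56.9-fold. Of 29 Toll-like receptor genes 16 rose and 4 fell (adjusted p = 7.0e-04; adjusted p = 0.157 with an estimated correlation). The inhibitory kinase Irak3 rose 7.57-fold, the lipopeptide receptors Tlr2 and Tlr1 6.26-fold and 6.12-fold, and the LPS co-receptor Cd14 6.04-fold. Of 24 stress genes 10 rose and 2 fell (adjusted p = 0.00384; adjusted p = 0.281 with an estimated correlation), among them the cystine transporter Slc7a11 at 24.0-fold, Mt2 at 3.46-fold, Gdf15 at 3.20-fold and the haem oxygenase Hmox1 at 2.40-fold. Of 26 cell cycle genes 13 fell and 1 rose (median -0.66, or -0.53 with bounded genes at their bound; adjusted p = 0.0231; adjusted p = 0.404 with an estimated correlation). Ccnd1 fell 3.26-fold, E2f1 2.81-fold, the replication helicase subunit Mcm4 2.56-fold and Stmn1 at least 1.69-fold.

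Apart from the neutrophil and sex-linked lists, the lists that camera tested but did not call for LPS held changes in both directions. Of 26 IL-4-induced genes 8 rose and 7 fell, with the arginine transporter Slc7a2 up 27.0-fold, Fgl2 up 7.44-fold, Cish up at least 4.69-fold and the lipid receptor Pparg down 5.39-fold. Of 10 MHC class II genes 4 rose and 3 fell, with Cd86 up 13.3-fold, H2-Ab1 up 2.86-fold and Ctss down 2.38-fold. Of 15 LXR and lipid genes 7 fell, the cholesterol ester hydrolase Nceh1 8.42-fold and the exporter Abcg1 at least 2.96-fold, and 1 rose, Nr1h3 at 2.57-fold. Of 27 scavenging genes 12 fell and 5 rose, with Fcgr2b up 8.15-fold, Gas6 down 5.77-fold and Stab1 down 4.11-fold. Of 23 macrophage identity genes 10 fell and 6 rose, with the fractalkine receptor Cx3cr1 down 9.37-fold, Cebpa down at least 4.39-fold and Cebpb up 3.47-fold. Of 22 remodelling genes 7 rose and 3 fell, with the collagenase Mmp13 up 48.3-fold, Mmp14 up 7.79-fold and the urokinase receptor Plaur up 6.67-fold. Of 18 glycolysis genes 6 rose and 2 fell, with the glucose transporter Slc2a1 up 4.17-fold and Pfkp up 3.56-fold.

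Among the smaller LPS groups, 4 of 23 RhoA and actin genes rose and 8 fell (Rac2 up 3.67-fold, Rhob down 4.32-fold). Of 14 microRNA machinery genes 4 rose and 3 fell (Prkra down 4.30-fold), and of 19 cholesterol genes 4 rose and 3 fell (Srebf2 up 2.13-fold). In these 3 lists the median was below 0 while camera's direction was up. Of 6 neutrophil genes 3 rose (Camp 2.58-fold, S100a8 2.35-fold, Csf3r 2.28-fold), and of 15 fibroblast genes 2 rose and 3 fell (Dcn 1.99-fold). Of 13 housekeeping genes 1 rose and 4 fell, Hprt 2.58-fold, and of 4 sex-linked genes 1 fell, Kdm5d 2.08-fold. The log2 level of Kdm5d was 7.06 on the WT mimic media array and 5.77 on its mock partner. On the LPS mock and mimic arrays it was 5.29 and 5.43. Comparisons of Kdm5d with WT media, also for IL-4 and the knockout, therefore lean on the WT mimic media array. The histamine enzyme Hdc rose 83.3-fold and Lck at least 2.46-fold, Il7r fell 4.30-fold and Itgax gave -0.32. Adjusted over the list alone, the counts were the same except for 6 and 9 RhoA genes, 4 and 4 microRNA genes, 1 and 2 cholesterol genes, 11 and 2 stress genes, 8 and 4 remodelling genes, and 2 and 1 fibroblast genes up and down.

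The split between directions after LPS depended on scaling. The median of all genes was -0.16, against -0.48 with median scaling and -0.27 without normalization, and the share of calls that rose was 39.1%, against 21.4% and 23.8%.

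IL-4 comparisons show the M2 side of polarization in WT cells. IL-4 changed 186 genes (limma), 122 up and 64 down, and 97 and 42 of these by more than 2-fold. Without the WT mock media array 191 rose and 253 fell, so which direction held more genes changed. Arg1, which splits arginine into ornithine and urea, rose at least 51.0-fold (6.21 ± 0.19 on the log2 scale, SE, 2 arrays against 2, adjusted p = 8.5e-07), and the secreted Retnla at least 55.0-fold. Chil3, a chitinase-like protein, rose 53.5-fold (5.74 ± 0.17). The LPS co-receptor Cd14, the receptor Tlr2, and Il1b and Ccl3 fell, among 2 of 29 Toll-like receptor genes and 4 of 26 cytokines.

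The VEGF receptor Flt1 rose 16.7-fold after IL-4 (4.06 ± 0.22), the ribonucleases Rnase2a and Ear2 at least 11.3-fold and 9.93-fold, and the kinase Matk 8.99-fold. The transcription factor Batf3 rose at least 7.67-fold, Egr2 8.25-fold and the STAT5 inhibitor Cish at least 6.23-fold. Arg1, Retnla, Rnase2a, Ear2, Batf3 and Cish were detected on 0 of 2 media arrays, and Egr2 on both. Mrc1 rose 5.58-fold (2.48 ± 0.26, adjusted p = 0.00169). Cx3cr1 fell 7.29-fold (-2.87 ± 0.32, adjusted p = 0.00266), Il1b at least 4.74-fold and the fungal mannan receptor Clec4n 4.40-fold. Cd14 fell 3.93-fold, Fpr2 3.54-fold, Fos 3.34-fold, the kinase anchor Akap12 3.22-fold, Ccl3 3.17-fold and Tlr2 3.10-fold. Gsta3 fell 3.35-fold and was detected on 1 of 2 IL-4 arrays. Rock2 gave -0.34 ± 0.22 (adjusted p = 0.544) and Ccl2 0.99 ± 0.27 (adjusted p = 0.131).

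Camera called 5 lists for IL-4, of which only the IL-4-induced genes held with an estimated correlation. In that list 18 of 26 rose, 24 adjusted over the list alone, and the median was 1.59, or 1.26 with bounded genes at their bound (adjusted p = 5.5e-40; adjusted p = 0.0126 with an estimated correlation). Of 10 MHC class II genes 5 rose, 6 adjusted over the list alone (median 1.16; adjusted p = 9.0e-07; adjusted p = 0.478 with an estimated correlation). The antigen-presenting chains H2-Ab1, H2-Eb1 and H2-Aa rose 5.29-fold, 3.98-fold and 3.44-fold, and the peptide loader H2-DMa 3.59-fold. Over the alternatives the MHC class II median ran from 0.26 to 1.58, and that of the IL-4-induced genes from 0.73 to 1.74. Of 26 cytokines 4 fell (median -0.20; adjusted p = 0.00375; adjusted p = 0.682 with an estimated correlation), among them Ccl4 at 2.75-fold and Tnf at 2.30-fold, and 7 fell and 2 rose adjusted over the list alone. That call was lost in 6 of 8 alternatives (median -0.30 to -0.02, adjusted p 5.3e-04 to 0.682), and without the WT mimic media array the median was -0.02. Of 15 fibroblast genes 0 passed and 13 were lower (median -0.28; adjusted p = 0.00375; adjusted p = 0.368 with an estimated correlation), with Fbln2 at -0.71 and Col3a1 at -0.70. Of 19 cholesterol genes 0 passed and 14 were lower (median -0.26; adjusted p = 0.0183; adjusted p = 0.733 with an estimated correlation), with Sqle at -0.64.

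Other lists had few genes past the threshold for IL-4. Of 28 NF-kB targets 2 rose and 2 fell, with Slc7a2 up 5.29-fold, Ier3 up 3.32-fold, Nfkbiz down 2.52-fold and Fpr2 as above. The inhibitory Fc receptor Fcgr2b rose 5.05-fold and the integrin Itgax 5.10-fold, while Gas6 fell 1.92-fold and the scavenger receptor Stab1 1.74-fold. Abcg1 was the LXR gene that rose, 1.95-fold, and Tfrc, the transferrin receptor, the housekeeping gene, 1.99-fold. Cd14 and Tlr2 were the Toll-like receptor genes that fell, and Cx3cr1 and Cd14 the macrophage identity genes. None passed among interferon-stimulated genes (Ifit3 -1.17, adjusted p = 0.0513; Rsad2 -0.78), RhoA and actin genes (Rhob -0.76), microRNA machinery (Tarbp2 0.58; median and mean opposite in sign) or cell cycle genes (Stmn1 -0.75). The same held for stress genes (Gdf15 -0.85), glycolysis genes (Ndrg1 -1.05, Pfkp 1.04), remodelling genes (Mmp13 1.65, Igf1 0.95), neutrophil genes (S100a8 -0.64), sex-linked genes (Kdm5d -0.67), Il7r (-0.40) and Hdc (-0.25). Adjusted over the list alone, 3 NF-kB targets, 2 Toll-like receptor, 1 glycolysis, 2 scavenging and 2 remodelling genes rose, and 2, 3, 2, 4 and 3 fell, with 1 interferon-stimulated, 4 macrophage identity, 1 neutrophil and 1 fibroblast gene. Camera's direction opposed the median in the microRNA and remodelling lists, and the mean opposed the median in the LXR list. The median of all genes was -0.01, against -0.17 with median scaling and -0.11 without normalization, and those settings left 102 and 31 genes past the threshold. Leaving out 1 array gave 444 genes without the WT mock media array, 69 without WT mock IL-4, 59 without WT mimic media and 55 without WT mimic IL-4.

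**Figure D3:**
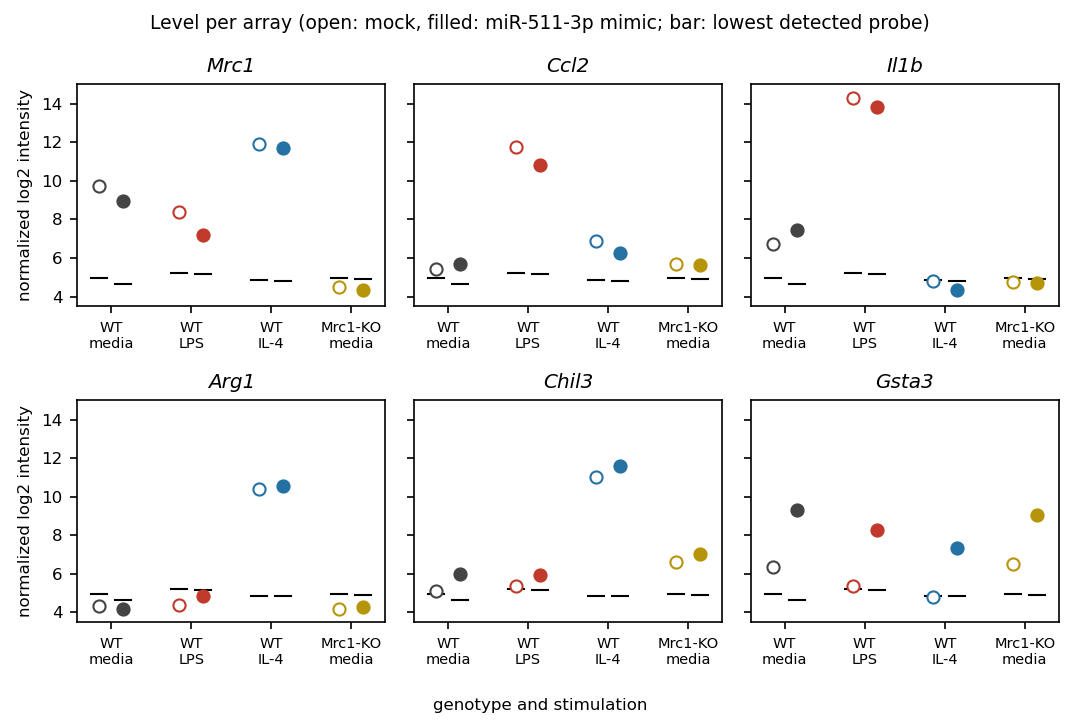
Normalized log2 intensity (vertical axis) of single genes on each of the 8 arrays (horizontal axis, by context), open points for mock, filled for mimic, and bars for the lowest detected probe of that array. Mrc1 was at background on both knockout arrays, and Gsta3 was higher on the mimic array of each pair.

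The knockout comparison asks what loss of Mrc1, the host gene of miR-511, changed in unstimulated cells. By limma 4 genes changed. Each genotype had 1 mock and 1 mimic array, and the labels name no separate mice or cultures. For genes other than Mrc1, a genotype effect therefore cannot be told apart from a difference between mice or cultures. Mrc1 fell at least 21.3-fold (-4.94 ± 0.26 on the log2 scale, SE, 2 arrays against 2, adjusted p = 1.8e-04). Vsig4, a complement receptor of tissue macrophages, rose 3.97-fold (1.99 ± 0.17, adjusted p = 0.00465) and was detected on 1 of the 2 WT arrays. Il1b fell at least 4.43-fold (adjusted p = 0.0489) and Erdr1 at least 3.51-fold (adjusted p = 0.00556). At an unadjusted p under 0.05 there were 400 genes, 4.77% of those tested.

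The next largest knockout differences did not pass. Among the higher genes, the ribonuclease Ear2 was at least 3.27-fold higher, detected on 0 of 2 WT arrays, and Ear4 gave 1.61, the neutrophil granule genes Ltf and Ngp 1.37 and 1.15 and the adhesion molecule Vcam1 1.33. Chil3 gave 1.25 (adjusted p = 0.0943), the transporter Slco2b1 1.22, and the calcium-binding S100a9 and S100a8 1.14 and 1.09. Among the lower ones, Saa3 gave -1.52, Ccl5 -1.27, Tmem254a -1.20 and the antiviral Rsad2 -1.09. Cxcl10 was at least 1.80-fold lower, Ifi214 at least 1.67-fold and Mid1 at least 1.42-fold, with 0 of 2 KO arrays detected. Rock2 gave -0.18 ± 0.22 (adjusted p = 0.878) and Ccl2 0.09 ± 0.27 (adjusted p = 0.965).

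Camera called 4 lists for the knockout, and 0 of them with an estimated correlation. Interferon-stimulated genes were lower in 31 of 35 cases (median -0.36; adjusted p = 5.1e-08; adjusted p = 0.804 with an estimated correlation), with 0 past the threshold and Ifit2 at -0.82. Neutrophil genes were higher in 5 of 6 cases (median 1.12; adjusted p = 3.6e-07; adjusted p = 0.637 with an estimated correlation), and 4 rose adjusted over the list alone. With no filter the median was 0.19, and the call was lost in 2 of 8 alternatives. Cytokines were lower in 22 of 26 cases (median -0.15; adjusted p = 9.5e-04; adjusted p = 0.804 with an estimated correlation), with Il1b past the threshold and 3 fallen adjusted over the list alone. That call was lost in 6 of 8 alternatives (adjusted p 0.00157 to 0.906), and without the WT mimic media array the median turned to 0.02 (adjusted p = 0.383). MHC class II genes were higher in 8 of 10 cases (median 0.24; adjusted p = 0.00323; adjusted p = 0.804 with an estimated correlation), with H2-Ab1 at 1.06 and H2-Eb1 at 0.98, and 4 rose adjusted over the list alone. That call was lost in 3 of 8 alternatives, with a lowest median of 0.05.

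Of the remaining lists only the IL-4-induced genes held a gene past the threshold for the knockout, Mrc1 itself. There the mean was -0.10, the median 0.01, with a sign that depended on the scaling, and camera's direction up. In the stress and LXR lists camera's direction opposed the median. Adjusted over the list alone, 2 IL-4-induced genes rose and 1 fell, and 2 fibroblast genes fell. Values of the most moved members were 0.93 for the iron-binding Lcn2, -0.43 for Tlr7, 0.58 for Rac1, -0.55 for the kinase Rock1, -0.31 for Ago2, -0.65 for Pcna and 0.53 for Srebf2. They were 0.60 for Nr1h3, -0.56 for Txnrd1, -0.34 for Hif1a, 0.44 for Maf, -0.73 for Vegfc and 0.19 for Itgax. Il7r gave -0.33, Hdc -0.20, Fbln2 -0.86, Tfrc 0.32 and Kdm5d -0.65. The median of all genes was 0.01, against -0.18 with median scaling and -0.11 without normalization. Without the WT mimic media array 0 genes passed and Mrc1 had an adjusted p of 0.0789, the highest over its alternatives (2.3e-06 to 0.0789). Without the KO mock array 2 genes passed, and without the KO mimic array 1.

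Since the mimic adds miR-511-3p and the knockout removes its host gene, their effects were set against each other on arrays that they do not share. Across genes, the knockout effect and the mean mimic response of the LPS and IL-4 pairs had a Pearson's r of 0.0457 and a Spearman's rho of 0.0179. Without Mrc1 the Pearson's r was 0.0408. The knockout effect averages a mock arm and a mimic arm, and in the mimic arm both genotypes received miR-511-3p. The level of the microRNA was not measured here, so an r near 0 does not exclude opposite effects. The knockout effect of the mock arm against that of the mimic arm gave 0.126, while the same comparison gave 0.889 for LPS and 0.443 for IL-4.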

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

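The fits without the WT media pair and with array weights, the list counts with median scaling or without the WT mimic media array, and 3 alternatives for the cytokine median were chosen after the data were seen, and the others before. The cause was not tested for any change given here, except that fewer arrays or genes enter some fits by construction. No named gene that passed in either setting changed direction, but 2 called lists' medians did. The mimic's neutrophil median, 0.46, became -0.037 with no filter, over 15 genes, and the knockout's cytokine median, -0.15, became 0.025 without the WT mimic media array.

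The mimic's 71 genes became 217 with normexp, 195 without background correction, 119 with detection on all 8 arrays, 209 with a trended and robust variance model and 371 with array weights. Of the 71, 70, 61, 58, 71 and 71 were called in the same direction there. With median scaling, no filter, WT arrays only, or without the WT media pair, 1 gene passed, Gsta3. Limma called 0 without normalization (588 at an unadjusted p under 0.05) and 0 without the context term (289). In those 2 settings Gsta3 did not pass, with adjusted p of 0.143 and 0.883 (3.2e-06 to 0.883 over its alternatives). Leaving out 1 array gave 1 to 2. Of the 20 genes named as changed, 0 passed in every setting.

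LPS gene counts stayed within 1.5 times of 4162, from 3052 to 4235. With every probe tested separately, 5487 of 11417 probes passed. Of the named calls 22 of 22 held. In some setting 20 of the 22 had a fold over 1.5 times smaller, and 2 a fold over 1.5 times larger. Without background correction Cxcl9 went from 7.14 to 5.12, Il1a from 7.24 to 5.30, Cxcr4 from -5.62 to -4.03 and Sesn1 from -5.01 to -3.17. A fold over 1.5 times smaller in some setting was also found for 15 of 21 named calls for IL-4, 4 of 4 for the knockout and 5 of 20 for the mimic. A fold over 1.5 times larger was found for 3 of the IL-4 calls and 0 of the knockout's or the mimic's. IL-4's 186 became 102 with median scaling, 31 without normalization, and 118 both with no filter and with detection on all 8 arrays. Leaving out 1 array gave 55 to 444: 444 without WT mock media (191 up and 253 down, against 122 and 64), 69 without WT mock IL-4, 59 without WT mimic media and 55 without WT mimic IL-4. Of its 21 named calls 12 held throughout. The knockout's 4 became 1 without background correction, 1 without normalization, 2 with no filter and 0 with detection on all 8 arrays, a filter that Mrc1 cannot meet. Leaving out 1 array gave 0 to 4: 0 without WT mimic media, 2 without KO mock and 1 without KO mimic. Of the knockout's 4 named calls 0 held in every setting. Without background correction its Il1b change went from -2.35 to -1.06 and its Erdr1 change from -2.16 to -0.89. The interactions stayed at 0.

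Lists called for the mimic, 3, became 0 with an estimated correlation, 1 with fry, 5 without background correction and 6 without normalization, and leaving out a pair gave 3 to 5 (5 without the WT media pair). The 6 for LPS became 0 with an estimated correlation and 16 with fry. The 5 for IL-4 became 1, 3 and, with detection on all 8 arrays, 3. The 4 for the knockout became 0 and 0. The cytokine median in the LPS pair, -0.48, became -0.19 with detection on all 8 arrays, where 10 genes were left. The correlation between contexts stayed within its spread over context pairs. That of knockout and mimic lay between 0.0377 and 0.0622, within an interval over genes taken as independent (0.0244 to 0.0671). The seed-site alternatives were not run. Signal over background limits calls of dim genes, since 35.7% to 45.1% of probes were detected.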

Other observations

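The limit to splits that part every pair, the tests of the brighter array, of normalization and co-variation for the interferon genes, of a second neutrophil list, and the further settings of the seed test were chosen after the results were seen, and the test over all splits, those of the seed match in probes and of genes near Mrc1 before.

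Some differences in single pairs belong to no tested comparison, and the genes here were chosen after their values were seen. In the LPS pair the potassium channel Kcnk13 was higher with the mimic by 2.30 on the log2 scale, the oxidative stress gene Osgin1 by 1.49 and the matrix protein Tgfbi by 1.12. Ifnb1, the interferon beta gene, gave -1.56 there, the transcription factor Mycl -1.48 and Mmp13 -0.90. In the IL-4 pair Irf7 gave -1.66, Il10 -1.45, Isg15 -1.17 and Ifit3 -1.10. Each is 1 array against 1, and 0 genes passed the interaction tests by limma (614 for LPS and 174 for IL-4 at an unadjusted p under 0.05). Genes past the threshold for the mimic that the report does not name include the cholesterol transfer protein Stard3 (-0.92) and the cargo receptor Surf4 (-0.85), which fell.

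The first pattern is the set of 71 genes called for the mimic. The model pairs arrays by context, and 8 splits of the arrays part every pair, too few for a share under 0.05. The real one gave 71 genes and the highest other 0, with 1 of the 8 as large. Counting all 32 splits that could be fitted was the test written first, but most of them cut across that pairing. The WT media mimic array was brighter than its partner. The called genes' median log2 change in their called direction was 0.796 in the other 3 pairs, against 0.882 in the media pair, but they were selected using all 4 pairs, so this excludes nothing. Without the media pair 1 gene passed, but without any other pair 1 or 2 did. The 71 genes' median SE was then 0.117, against 0.121, and the residual degrees of freedom fell from 3 to 2. Array weights, lowest for the media pair (0.420), gave 371 genes, among them all 71. A part of that array in the count, an effect of miR-511-3p and an effect of transfecting any short RNA stay open. The labels call the control a microRNA mock and tag it mi-neg without describing it, so whether it held a short RNA, which would cancel the last of these, is not settled here.

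The second pattern is the lower level of interferon-stimulated genes with the mimic. Without normalization their median less that of all genes (0.07) was -0.144, so the quantile step does not make the direction. They vary together, with an estimated correlation of 0.276 between genes. That value comes from the residuals, which include differences between contexts in the mimic response. The camera alternative with estimated correlations gave an adjusted p of 0.645. That alternative also raised the p of lists whose estimated correlation was below the preset 0.01, so co-variation alone need not explain it. The same setting gave 0.157 for the LPS cytokines, all 26 of which rose, so it has little power here. It cannot tell a shared swing in interferon signalling between samples from a response to the mimic, and both stay open.

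The third pattern is the higher level of neutrophil genes in the knockout. Cells of that type would bring their other abundant transcripts, so a second list of 30 markers was written before it was tested. Of these 7 were tested and 4 were higher, with a median of 0.07 at percentile 70.0 of random lists. Lcn2 gave 0.93, Mmp9 0.47, Lyz2 0.09, Gca 0.07, Anxa1 -0.18, Hp -0.20 and Clec4d -0.28, and macrophages express several of these, while Lcn2 and Mmp9 are also in other fixed lists. The test leaves more immature neutrophils in the culture and a change within macrophages open.

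Direct targets of the mimic could carry its seed match within the probed part of their transcript. In 22 tested genes the probe held the 7-base match TACACAT. Their median mimic effect was -0.13, and 18 of 22 were lower, against 49.8% of all genes. That median was at percentile 0.577 among 6928 other 7-base words, each held by as many genes or more. Stard3 and Surf4 were the 2 that fell. Per context the median was 0.03 in WT media (percentile 71.3), -0.16 in LPS (0.736), -0.32 in IL-4 (0) and -0.17 in the knockout (0.202). Without the WT media pair it was -0.20 (percentile 0), and after removing trends with level and GC content -0.15 (percentile 0.231). Without normalization it was 0.01 (percentile 1.85), with 9 of 22 lower. It lay below all 20 words of the same composition (percentile 0), while the reverse complement, in 30 genes, had a median of 0.09 (percentile 95.9). Repression through the seed would give such lower values, on few genes. The words compared with were held by as many genes or more, so their medians may spread less. The percentiles may therefore be too extreme, and repression through the seed is not settled here.

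A deletion or flanking strain DNA at Mrc1 could change neighbouring genes in the knockout. If donor-strain DNA around Mrc1 did so, the neighbours would pass more often than other genes. Among the 100 genes on either side of Mrc1, 18 were tested, and 1, H2al2a, had an unadjusted p under 0.05, or 5.56% against 4.76% of the other genes (Fisher's exact p = 0.585). With so few neighbours the test decides nothing.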
